A study of Homo sapiens with 9 samples.

How the data were processed

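The study sequenced RNA from HEK293T cells, a human embryonic kidney cell line, after ribosomal RNA had been removed. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a directional kit from input, supernatant and immunoprecipitated RNA. The labels tie 6 libraries to an FHY1-M3 construct with an ACTB, con or non-target guide RNA (sgRNA), with 2 libraries for each guide. They call 3 further libraries input. They do not say whether the 6 FHY1-M3 libraries hold total or immunoprecipitated RNA, which light each culture received, or how the con guide differs from the non-target guide. In the count table the con columns carry the name con_ACTB_sgRNA, while the sample titles say con_sgRNA, so whether the con libraries also had the ACTB guide is not known. Nothing says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

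The deposited values are whole-number read counts per gene for 19969 gene symbols in 9 libraries, not normalized by the authors as far as the values show. The submitters' processing notes name cutadapt 4.3, STAR 2.7.10b, deepTools and the build hg38, without saying what each was used for. The counting tool, its strand setting and the gene annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping genes cannot be told apart. Among genes with 1 to 20 counts, 88.5% to 95% of the values per library were even. Both mates of a read pair therefore appear to have been counted, so that a fragment adds about 2 counts, and intervals or floors from counts cover counting error only. Of the symbols, 19295 matched a reference gene table (GRCh38.p14), directly or through an older name, and 674 did not. Gene coordinates are from that table and are 1-based.

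Total counts ran from 2900021 to 3802681 in the sgRNA libraries and from 350413 to 643954 in the inputs, so values in the inputs are the less precise ones. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.8 and 5.12 on counts halved to read pairs. No library was therefore treated as a repeat of another.

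Groups were compared with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3 on the deposited counts, two-sided, after removal of low-count genes by group and with TMM scaling. Comparisons between guides used 1 fit of the 6 sgRNA libraries, and comparisons with input used 1 fit of all 9. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Every adjusted p of a single gene in the text is from this test unless another tool is named. The standard error (SE) of a log2 fold change was taken from the fold change and its F statistic. Levels are CPM, counts scaled to a common library total within the fit, given as mean ± SD. When every library of a group was at 0, the fold is a lower bound against 3 counts over that group, written as "at least". Both mates of a read pair appear to have been counted, so 3 counts stand for fewer than 3 fragments. A floor of 3 fragments would lower every such bound in the text, and bounds on that floor were not computed. With 1 to 3 counts the ratio carries a 95% counting interval.

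Genes were named by a rule: up to 8 genes per direction with the largest fold among those past the threshold, with a mean of at least 5 CPM and no overlap between the libraries of the groups. Symbols ending in P and a digit were excluded to keep out pseudogenes. Up to 4 members were named per list past its threshold, and for the m6A machinery and the actins, a list that includes actin-related genes. Gene lists (33, of which 27 had at least 5 measured members) were tested with limma 3.58.1 camera, with a preset correlation of 0.01 and again with an estimated one, and with fry. These choices, the comparisons and most of the alternatives were fixed before the data were examined. Alternatives covered scaling, low-count filters, DESeq2 1.42.0, the libraries in the fit, a replicate block and leaving out each library in turn. Alternatives chosen after seeing the data were counts halved to read pairs, sgRNA libraries thinned to 462026 counts, removal of mitochondrial and histone genes, a minimum mean of 10 CPM, and the halved counts and left-out libraries for the gene lists.

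The test was tried on simulated counts with 200 changed genes, drawn only from genes above a minimum mean count. The shares recovered therefore do not cover low-count genes. Counting of both mates was not simulated. For ACTB sgRNA against non-target sgRNA (12520 genes), 14%, 46%, 62% and 88% of genes changed by 1.5, 2, 4 and 8 times were recovered, with 2 false calls. For the FHY1-M3 libraries against input (13011 genes), the shares were 10%, 30%, 72% and 92%, with 6 false calls. m6A levels at single sites were not analysed here.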

Results

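Gene counts were compared across 9 ribosomal-RNA-depleted libraries of HEK293T cells. Of these, 6 came from cells with an FHY1-M3 construct, 2 each with a guide RNA (sgRNA) against ACTB, a con sgRNA and a non-target sgRNA. The other 3 were input libraries. The series concerns editing of N6-methyladenosine (m6A), a methyl mark on RNA, under red and far-red light. FHY1 is the name of an Arabidopsis protein that binds the light receptor phytochrome A. The sgRNA libraries held 2900021 to 3802681 counts each, and the inputs held 350413, 643954 and 391710. The ratio of the median totals was 9.29.

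ACTB, which encodes cytoplasmic beta-actin and is the gene named by the guide (chromosome 7, 5527148 to 5530601, GRCh38.p14), was measured first. Its level was 1370 ± 55 CPM with the ACTB sgRNA, 1390 ± 2.36 CPM with the con sgRNA and 1350 ± 12.3 CPM with the non-target sgRNA (mean ± SD, n = 2 each). The log2 difference between ACTB and non-target sgRNA was 0.02 (SE 0.06), with a 95% interval of -0.1 to 0.14 and an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.962. Against the con sgRNA it was -0.02 (SE 0.06), with an interval of -0.14 to 0.09 and an adjusted p of 1. Between con and non-target sgRNA it was 0.05 (SE 0.06), with an interval of -0.07 to 0.17 and an adjusted p of 0.988. No difference between guides in the share of counts from ACTB was detected, and the intervals leave room for folds between 0.906 and 1.12. The labels do not say whether these libraries hold total or immunoprecipitated RNA, so this share may not be the ACTB transcript level. The sign of the ACTB estimate against non-target changed to -0.02 without ACTB sgRNA replicate 1. Against the con sgRNA it changed to 0.01 without ACTB sgRNA replicate 2.

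ACTB sgRNA was compared with non-target sgRNA to see which transcripts differ when the construct is directed to ACTB. EMX1, a homeobox transcription factor of the developing forebrain, stood at 69.5 ± 1.5 CPM with the ACTB sgRNA and 11.4 ± 9.24 CPM with the non-target sgRNA (log2 2.64, SE 0.39, adjusted p = 3.46e-05, n = 2 each). RUNX1, a transcription factor of blood formation, was at 46.5 ± 1 against 13 ± 2.19 CPM (log2 1.84, SE 0.42, adjusted p = 0.0335). Smaller rises were measured for PPP2R1A, a scaffold subunit of protein phosphatase 2A (log2 0.66, SE 0.16), and UBE2S, a ubiquitin-conjugating enzyme (0.54, SE 0.12). MT-CO1, a mitochondrial subunit of cytochrome c oxidase (0.25, SE 0.06), and EEF1A1, a translation elongation factor (0.14, SE 0.03), also rose. Several developmental transcription factors were at 0 in both ACTB sgRNA libraries and present in both non-target libraries. KLF1, the erythroid transcription factor, stood at 66.5 ± 5.13 CPM with the non-target sgRNA and was at least 156-fold lower with the ACTB sgRNA (adjusted p = 3.02e-10). MEOX2 and FOXI1 were at least 89.2-fold and 88.5-fold lower, LHX5 at least 83.5-fold and LYL1 at least 67.9-fold. The growth factor gene FGF3 was at least 66.5-fold lower and FOXS1 at least 64.4-fold lower. FEZF2, named after its values were seen, held 4 counts with the ACTB sgRNA and 766 with the non-target sgRNA (log2 -7.58, SE 0.6). KLF1, MEOX2, FOXI1, LHX5, LYL1, FGF3 and FEZF2 held 0 or 1 counts with the con sgRNA. EMX1 was high with the con sgRNA too (302 and 253 counts, against 244 and 241 with the ACTB sgRNA). EMX1 and the genes at 0 or 1 counts with the con sgRNA therefore set the non-target libraries apart from the ACTB and con libraries alike. Whether the con libraries also had the ACTB guide is not known. For these genes an effect of the ACTB guide therefore cannot be told apart from a trait of the non-target libraries. In all, 32 of 12808 genes passed the edgeR quasi-likelihood test between ACTB and non-target sgRNA, 7 higher and 25 lower, with 1001 at an unadjusted p under 0.05. DESeq2 called 74 genes, and only 16 passed when all 9 libraries shared the fit. The count was 19 without either ACTB sgRNA replicate and 18 without non-target replicate 1, against 35 without non-target replicate 2 or either con replicate. EMX1, KLF1, MEOX2, FOXI1, LHX5 and FGF3 kept their calls under every alternative. RUNX1 lost its call without ACTB sgRNA replicate 1 (adjusted p = 0.208) or 2 (0.317), con replicate 1 (0.0567) and non-target replicate 1 (0.292) or 2 (0.0798), and PPP2R1A without any of the 6 libraries (0.0947 and 0.68 for ACTB sgRNA replicates 1 and 2, 0.0812 and 0.0778 for con, 0.267 and 0.161 for non-target). Without ACTB sgRNA replicates 1 and 2 in turn, UBE2S (0.0857, 0.66), MT-CO1 (0.408, 0.0867) and EEF1A1 (0.229, 0.142) lost theirs. So did EEF1A1 (0.174) and LYL1 (0.155) without non-target replicate 1, and UBE2S (0.281), MT-CO1 (0.233) and EEF1A1 (0.0928) without replicate 2. With all 9 libraries in the fit PPP2R1A (adjusted p = 1), UBE2S (1), MT-CO1 (0.285) and EEF1A1 (1) lost their calls, and PPP2R1A also under median-ratio factors (0.0529) and with a mean of at least 10 CPM (0.0522). FOXS1 lost its call in DESeq2 (adjusted p = 0.247). The log2 fold change of EMX1 was 1.95 without non-target replicate 1 and 3.82 without replicate 2.

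**Figure D1:**
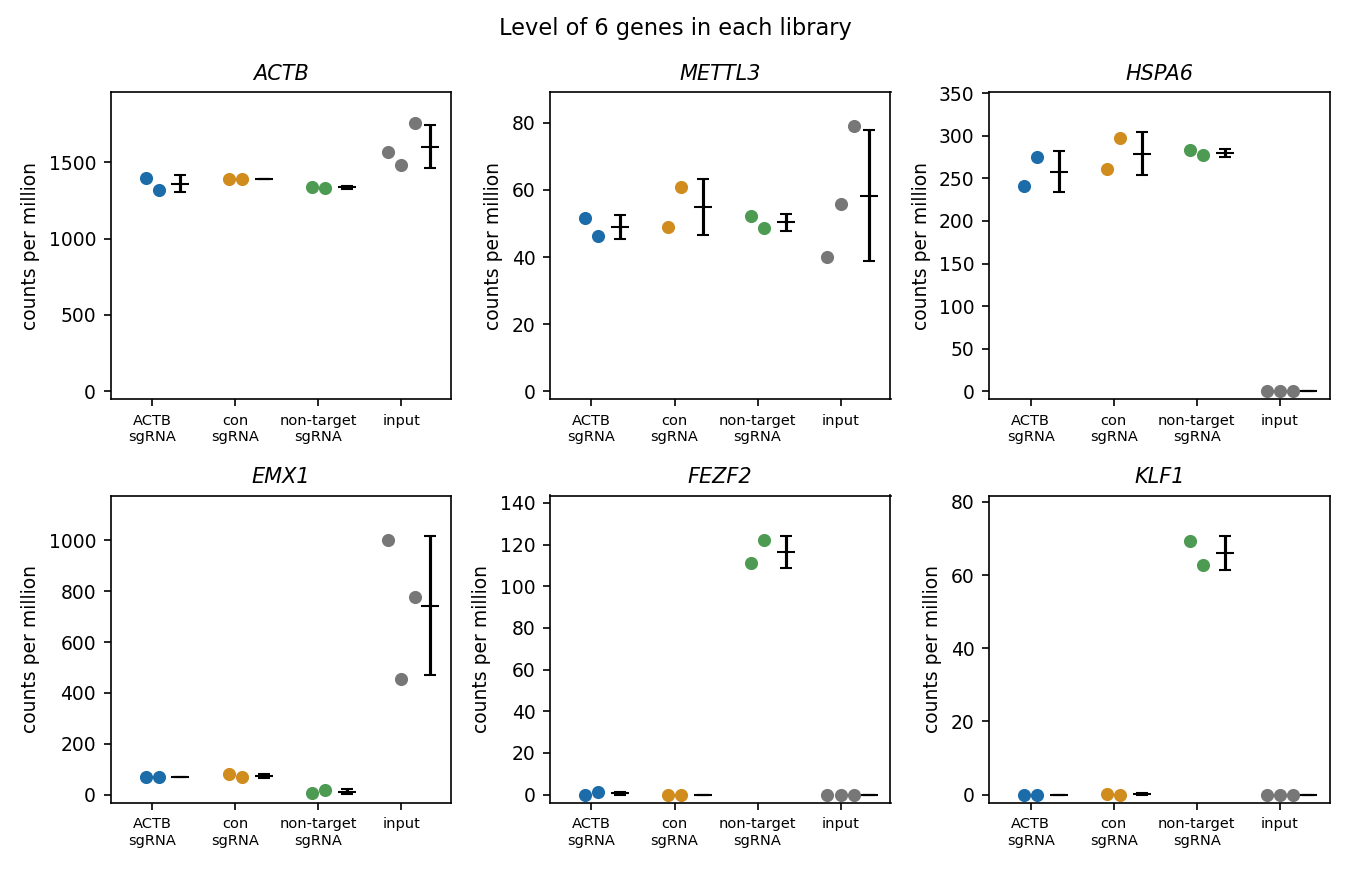
CPM, counts scaled to a common library total, for 6 genes (vertical axes) in the 3 sgRNA groups and the inputs, with a point for each library and the mean ± SD beside the points (n = 2, 2, 2 and 3). ACTB is alike in the sgRNA groups, HSPA6 is at 0 in all inputs, and FEZF2 and KLF1 are present in both non-target libraries and at or near 0 in the other groups.

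The con sgRNA was compared with the non-target sgRNA. EMX1 was the higher gene, at 73.3 ± 8.66 CPM with the con sgRNA and 11.4 ± 9.24 CPM with the non-target sgRNA (log2 2.71, SE 0.39, adjusted p = 1.58e-05, n = 2 each). FEZF2, a forebrain transcription factor, stood at 117 ± 7.29 CPM in the non-target libraries and at 0 with the con sgRNA, at least 294-fold lower (adjusted p = 1.42e-13). FOXE3, MEOX2 and FOXI1 were at least 98.3-fold, 96.7-fold and 96.0-fold lower, and LYL1 at least 73.7-fold lower. FGF3 was at least 72.2-fold lower, and LDB2, a cofactor of LIM-domain proteins, at least 62.9-fold lower. Of 12808 genes, 22 passed the edgeR quasi-likelihood test, 1 higher and 21 lower, and 673 had an unadjusted p under 0.05. This comparison and that of ACTB with non-target sgRNA use the same 2 non-target libraries, so their calls are not independent. Lower in both were 19 genes, against 0.041 for independent lists and, for lists of the same sizes in 20 simulations of 6 unchanged libraries, a mean of 0.5 and a highest value of 3, and part of the excess can come from the shared controls. DESeq2 called 38 genes, and 10 passed without non-target replicate 1, where LYL1 (adjusted p = 0.198) and FGF3 (0.0617) lost their calls. LDB2 lost its call without non-target replicate 2 (adjusted p = 0.0801). EMX1 was at a log2 of 2.03 without non-target replicate 1 and 3.90 without replicate 2.

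Between ACTB and con sgRNA few genes differed. JPH3, which encodes a junctophilin that links the endoplasmic reticulum to the plasma membrane, was at 179 ± 12.3 CPM with the ACTB sgRNA and 335 ± 85.6 CPM with the con sgRNA (log2 -0.90, SE 0.14, adjusted p = 0.00144, n = 2 each). MT-CO1 was higher at 1770 ± 69.3 against 1440 ± 26.6 CPM (log2 0.30, SE 0.06, adjusted p = 0.0132). The homeobox gene HOXC12 was at 11.7 ± 13.3 against 0.531 ± 0.751 CPM (log2 4.37, SE 0.81, adjusted p = 0.0132), with an SD above its mean. It held 80 counts with the ACTB sgRNA and 4 with the con sgRNA, but 438 with the non-target sgRNA, where it was highest. JPH3 lost its call without ACTB sgRNA replicate 1 (adjusted p = 0.271) or 2 (0.0698) and without con replicate 2 (log2 -0.62, adjusted p = 1). MT-CO1 lost it without ACTB sgRNA replicate 1 (0.612) or 2 (0.102) and con replicate 1 (0.182) or 2 (0.159). HOXC12 lost it without ACTB sgRNA replicate 2 (log2 2.01, adjusted p = 1), con replicate 1 (0.182) and non-target replicate 1 (0.141) or 2 (0.081), and in DESeq2 (0.65), and was at a log2 of 8.34 without con replicate 2. Of 12808 genes, 4 passed the edgeR quasi-likelihood threshold, these 3 among them, with 494 at an unadjusted p under 0.05, and DESeq2 called 5. None passed when all 9 libraries shared the fit or without ACTB sgRNA replicate 2, 1 passed without ACTB sgRNA replicate 1 or con sgRNA replicate 2, and 2 passed without either non-target replicate.

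No fixed gene list separated the guides. The m6A machinery (25 writers, erasers and readers) had 0 members past the threshold in each of the 3 comparisons, with 0 also when adjusted over the list alone. At an unadjusted p under 0.05 there were 3 for ACTB against non-target, 1 for ACTB against con and 2 for con against non-target sgRNA. Examples for ACTB against non-target sgRNA are the writer subunit gene RBM15B (log2 -0.34, SE 0.14, adjusted p = 0.54) and the reader genes HNRNPA2B1 (-0.14, SE 0.06) and IGF2BP2 (0.49, SE 0.21). METTL3, the catalytic m6A writer, differed by -0.05 (SE 0.32) between ACTB and non-target sgRNA, with an interval of -0.69 to 0.59. Of the 9 measured actin and actin-related genes, 0 passed in each of the 3 comparisons. There were also 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. ACTG1, the other cytoplasmic actin, differed by 0.06 (SE 0.05) between ACTB and non-target sgRNA. In limma camera, 0 of 27 lists passed in each comparison. The smallest adjusted p was 0.974 for ACTB against non-target sgRNA, 0.959 for ACTB against con sgRNA and 0.855 for con against non-target sgRNA. At an unadjusted p under 0.05 there were 1, 0 and 0 lists in that order, and with fry or an estimated correlation 0 passed. When adjusted over each list alone, ACTB against non-target sgRNA gave 1 higher and 3 lower heat shock genes (0 of 21 over all genes) and 2 higher translation factor genes (1 over all genes). Other lists with such genes included glycolysis with 1 higher gene (0 over all genes), mitosis with 1 lower (0), mitochondrial mRNAs with 1 higher (1) and fibroblast markers with 2 lower (1).

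The FHY1-M3 libraries together (n = 6) differed widely from the inputs (n = 3). HSPA6, an inducible heat shock protein gene (chromosome 1, 161524540 to 161526894, GRCh38.p14), stood at 270 ± 19.4 CPM in the FHY1-M3 libraries and at 0 in every input, at least 121-fold higher. At the FHY1-M3 level, 378 counts would have been seen over the 3 inputs, and 112 to 134 counts per library were left when the sgRNA libraries were thinned to the mean input total. Mitochondrial mRNAs took 0.61%, 0.58% and 0.58% of counts with the ACTB, con and non-target sgRNA and 7.67% ± 0.142 (SD, n = 3) in the inputs. Replication-dependent histone genes took 0.887% ± 0.0787 of the input counts and 0.135% ± 0.00354 with the ACTB sgRNA (n = 2). Heat shock genes went the other way, with 0.680% ± 0.00902 in the inputs and 1.45% ± 0.0255 with the ACTB sgRNA.

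**Figure D2:**
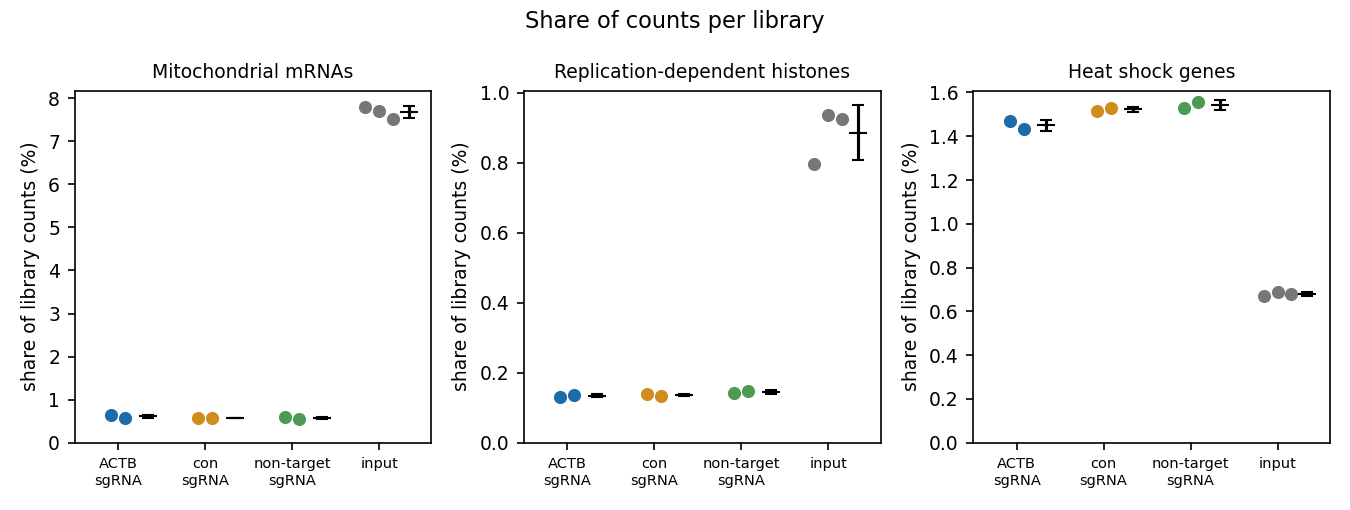
Share of each library's counts (vertical axes, percent) taken by mitochondrial mRNAs, replication-dependent histone genes and heat shock genes, with a point for each library and the mean ± SD beside the points. The inputs lie between 7.518% and 7.796% for mitochondrial mRNAs, and the sgRNA libraries between 0.563% and 0.639%.

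All 13 mitochondrial mRNAs fell, with a median log2 fold change of -3.92 and 13 also when adjusted over the list alone. Examples are MT-ND4 (-4.75, SE 0.05) and MT-ATP6 (-4.89, SE 0.07), with MT-CO1 at -3.34 (SE 0.04) and MT-ND5 at -3.51 (SE 0.05). Among replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, 37 of 43 fell and 0 rose, with 37 when adjusted over the list alone and a median of -2.75. HIST1H1E (-2.75, SE 0.11), HIST1H1C (-2.82, SE 0.12), HIST1H3B (-3.20, SE 0.14) and HIST2H2BE (-3.14, SE 0.14) were among them, and members of this family share sequence, so single values are uncertain. Of 21 heat shock proteins and cochaperones, 18 rose and 0 fell, with 18 when adjusted over the list alone and a median of 0.77. DNAJB1 rose from 139 ± 22.5 to 931 ± 49.5 CPM (log2 2.76, SE 0.12) and HSPH1 from 119 ± 46.8 to 693 ± 28.7 CPM (2.52, SE 0.15). HSP90AA1 rose by 1.62 (SE 0.07), and HSPA1B by 1.78 (SE 0.11), although it has a near-identical copy with which reads may have been shared. In camera the adjusted p was 5.08e-27 for the mitochondrial list, 1.16e-33 for the histone list and 5.62e-08 for the heat shock list. These 3 calls held with an estimated correlation (adjusted p = 0.00527, 0.0053 and 0.0127).

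A further 3 lists passed camera only with the preset correlation. Of 33 DNA replication genes 16 rose and 0 fell, with 19 rising and 1 falling when adjusted over the list alone and a median of 0.52 (camera adjusted p = 0.001, adjusted p = 0.0523 with an estimated correlation). The replicative helicase genes MCM7 (1.06, SE 0.11), MCM2 (0.96, SE 0.12) and MCM6 (1.40, SE 0.18) and the flap endonuclease gene FEN1 (1.58, SE 0.2) were among them. Of 78 cytosolic ribosomal protein genes 37 fell and 10 rose, with 41 falling and 11 rising when adjusted over the list alone and a median of -0.24 (camera adjusted p = 6.6e-06, adjusted p = 0.123 with an estimated correlation). RPL10 (-0.84, SE 0.07), RPS13 (-1.32, SE 0.12) and RPLP2 (-0.99, SE 0.1) fell, and RPS9 rose (1.02, SE 0.11). Of 432 ZNF zinc finger genes 76 rose and 24 fell, with 81 and 25 when adjusted over the list alone. Their median was 0.44, or 0.43 with genes at 0 in a group set at their bound (camera adjusted p = 0.0122, adjusted p = 0.123 with an estimated correlation). ZNF473 (2.63, SE 0.24), ZNF721 (1.62, SE 0.2) and ZNF317 (1.63, SE 0.21) rose, and ZNF587 fell (-2.91, SE 0.35). Each of these medians kept its sign under library-size scaling and under median-ratio factors, at 0.58 and 0.44 for DNA replication, -0.19 and -0.32 for ribosomal proteins and 0.49 and 0.36 for zinc fingers.

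The m6A lists did not pass camera, while fry, which does not compare a list with other genes, called both (adjusted p = 0.00485 for each). In the m6A machinery 9 of 25 genes rose and 2 fell, with 9 and 2 when adjusted over the list alone (median -0.04, mean 0.18, camera adjusted p = 0.781). RBM15B (1.60, SE 0.18), HNRNPA2B1 (0.67, SE 0.09) and the reader genes YTHDF2 (1.21, SE 0.17) and YTHDC1 (1.11, SE 0.18) rose. METTL3 differed by -0.24 (SE 0.31, interval -0.87 to 0.38, adjusted p = 0.631), and the demethylase gene FTO, named after its values were seen, fell by 1.06 on the log2 scale (SE 0.24). Of 28 transcripts often described as carrying m6A, 5 rose and 4 fell, with 7 and 4 when adjusted over the list alone (median 0.16, camera adjusted p = 0.968). ACTB was lower in the FHY1-M3 libraries, at 1350 ± 30.7 CPM against 1640 ± 136 CPM (log2 -0.28, SE 0.07, adjusted p = 0.00375). ACTR1B, an actin-related gene of the dynactin complex, rose by 1.07 (SE 0.32, adjusted p = 0.0158), and lost its call without input replicate 2 (adjusted p = 0.149) or 3 (0.0602), after thinning to the input depth (0.103) and with a replicate block (0.0561). The other 7 measured actin and actin-related genes did not pass, with 1 rising and 1 falling also when adjusted over the list alone (median 0.06, camera adjusted p = 0.918).

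**Figure D3:**
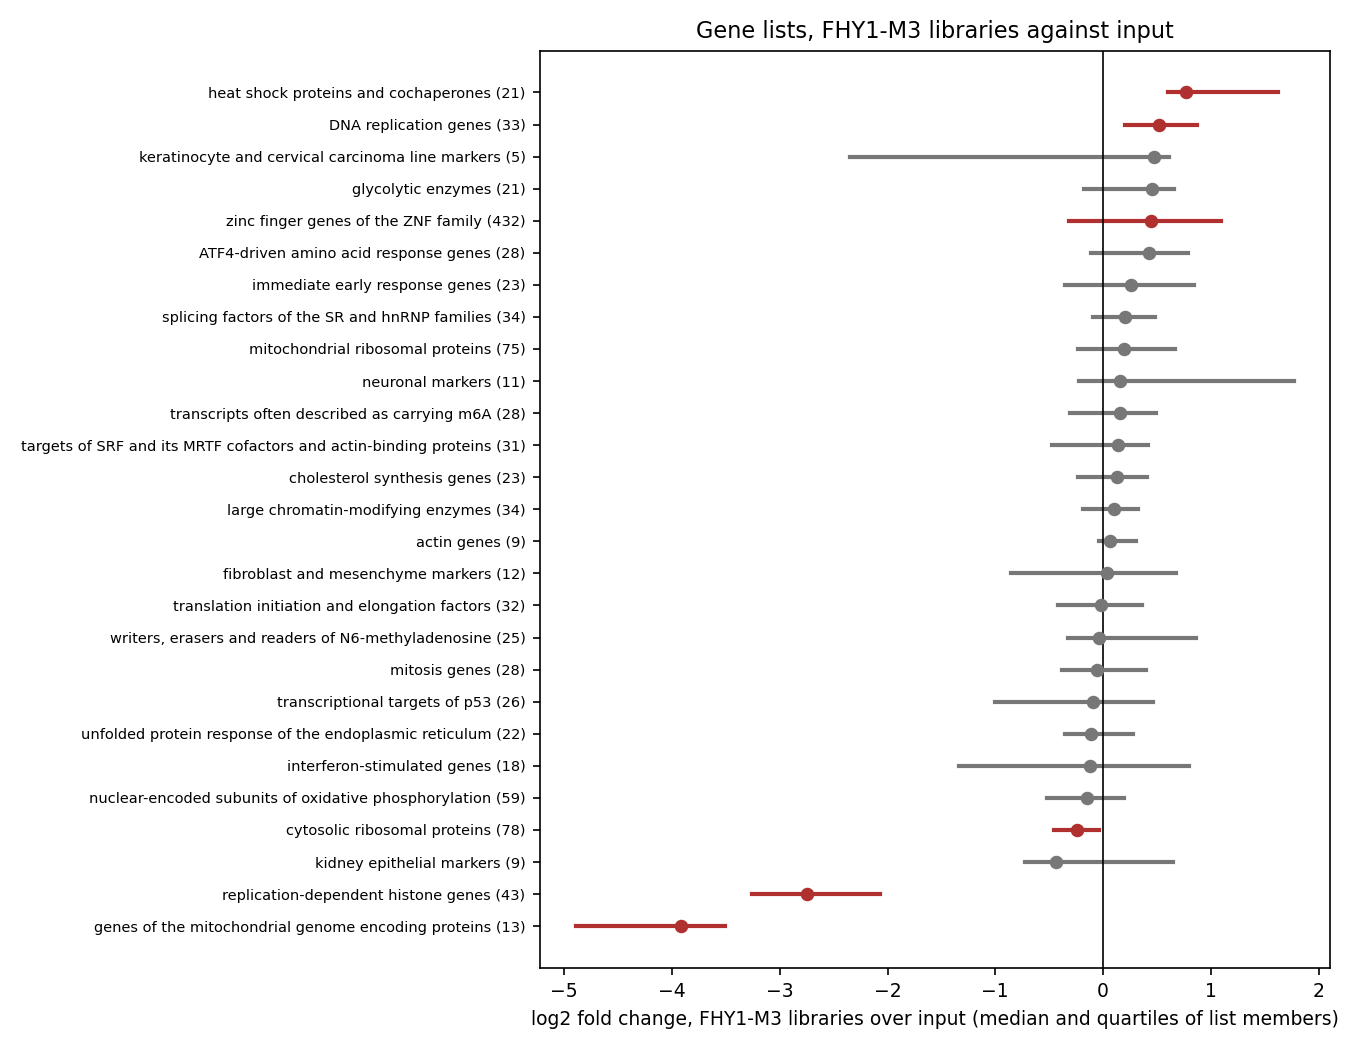
Median (point) and quartiles (line) of the log2 fold changes of FHY1-M3 libraries over input (horizontal axis) for the 27 gene lists tested, with the number of measured members in brackets and lists past camera's adjusted threshold of 0.05 in red. The mitochondrial list has its median at -3.92, the histone list at -2.75 and the heat shock list at 0.77.

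Among genes past the threshold whose FHY1-M3 and input libraries did not overlap, the largest bounds upward after HSPA6 belonged to genes at 0 in every input. HOXB13, a homeobox gene, was at least 10.6-fold higher, VWA1 at least 8.67-fold, ZNF695 at least 8.04-fold and SERTAD1 at least 7.54-fold. RHBDL1 was at least 6.51-fold, LOR at least 6.33-fold and FAM83B at least 5.68-fold higher. All of these bounds are against 3 counts, and a floor of 3 fragments would lower them. TMEM107 was among the lower genes (log2 -7.24, SE 0.24), at 9.13 ± 3.32 CPM against 1340 ± 893 CPM in the inputs. The small nucleolar RNA gene SNORD118 lies inside its bounds (chromosome 17, 8173452 to 8173588, within 8172457 to 8176380, GRCh38.p14). GPR34 (-7.36, SE 1.62), FBXO40 (-6.89, SE 1.42), PRH1 (-6.57, SE 1.59), IGSF6 (-5.98, SE 1.4) and PCDHB16 (-5.53, SE 1.51) were also lower, each with 30 or fewer counts over the inputs. KCNE1B (-6.31, SE 0.38) and SMIM11B (-5.92, SE 0.34) have near-identical copies, so their values are uncertain. PCDHB16 lost its call without con sgRNA replicate 2 (adjusted p = 0.0621) and with a replicate block (0.0608).

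Over all genes, 2677 of 13411 passed the edgeR quasi-likelihood test between the FHY1-M3 libraries and input, 1524 higher and 1153 lower, with 4284 at an unadjusted p under 0.05. The direction of the split was not stable, with 1251 higher and 1343 lower under median-ratio size factors, 1385 and 1568 in DESeq2 and 1012 and 1142 after thinning, while under median-ratio size factors the median of all genes moved from 0.037 to -0.042. With the sgRNA libraries thinned to the mean input total, 2154 genes passed, 1975 of them among the 2677, and the medians were 0.76 for heat shock genes, -4.01 for mitochondrial mRNAs and -2.98 for histone genes. Construct and library type are not separated by the comparison.

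Each guide was also set against the inputs on its own. HSPA6 was at least 114-fold, 123-fold and 125-fold higher with the ACTB, con and non-target sgRNA. The heat shock list had 15, 17 and 17 of 21 genes rising and 0 falling, with 18 rising in each when adjusted over the list alone (camera adjusted p = 5.02e-08, 1.27e-08 and 1.81e-08, n = 2 against 3). All 13 mitochondrial mRNAs fell with every guide, with 13 when adjusted over the list alone and medians of -3.96, -3.96 and -3.83. Of 43 histone genes, 35, 36 and 34 fell, with 36, 37 and 37 when adjusted over the list alone. With the non-target sgRNA, FEZF2 was at least 51.6-fold, KLF1 at least 29.6-fold, HOXC12 at least 29.5-fold and INSM2 at least 23.3-fold higher than in the inputs. FOXE3, FOXI1 and LHX5 were at least 17.2-fold, 16.8-fold and 15.9-fold higher. With the ACTB sgRNA, HOXB13 was at least 17.3-fold and VWA1 at least 8.35-fold higher, and TMEM107 was lower by a log2 of -7.55 (SE 0.4). With the con sgRNA, ZNF695 was at least 8.19-fold and VWA1 at least 8.07-fold higher, and WDR74 was lower by a log2 of -5.59 (SE 0.25). ACTB was at -0.29 (SE 0.09, adjusted p = 0.0368), -0.26 (SE 0.09, adjusted p = 0.0616) and -0.30 (SE 0.09, adjusted p = 0.0232) with the ACTB, con and non-target sgRNA, and these calls were not stable. The ACTB sgRNA call was lost under library-size scaling (adjusted p = 0.0877), without a low-count filter (0.0576), with a replicate block (0.142) and without ACTB sgRNA replicate 1 (adjusted p = 0.142) or 2 (0.346), con replicate 1 (0.0727) or 2 (0.0716), non-target replicate 1 (0.064) or 2 (0.054) and input replicate 3 (0.115). The non-target call of ACTB was lost with a replicate block (0.0981) and without non-target replicate 1 (0.153) or 2 (0.159) and input replicate 3 (0.081), whereas ACTB passed with the con sgRNA without input replicate 1 (0.0225) or 2 (0.0101), under median-ratio factors (0.0108), in DESeq2 (0.000491), with halved counts (0.0246) and after thinning (0.0118).

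The numbers of genes past the edgeR quasi-likelihood threshold against input were 1477 with the ACTB sgRNA (945 higher, 532 lower), 1534 with the con sgRNA (968 higher, 566 lower) and 1699 with the non-target sgRNA (1086 higher, 613 lower), of 13411. In DESeq2 there were 890 higher and 930 lower, 902 and 943, and 989 and 1065. When only the groups compared were fitted, lower genes outnumbered higher ones, with 336 higher and 434 lower for ACTB, 413 and 500 for con and 369 and 443 for non-target sgRNA. Leaving out a replicate of the guide lowered the counts to 682 (without replicate 1) and 630 (without replicate 2) for ACTB, 616 and 608 for con and 735 and 916 for non-target sgRNA. In each comparison 6 of 27 lists passed camera, and heat shock, mitochondrial and histone genes held with an estimated correlation. DNA replication genes had 14, 15 and 14 of 33 rising and 0 falling with the ACTB, con and non-target sgRNA (17, 18 and 16 rising and 0, 0 and 1 falling when adjusted over the list alone; adjusted p = 0.0619, 0.0545 and 0.054 with an estimated correlation). Ribosomal protein genes had 25, 23 and 28 of 78 falling and 5, 7 and 6 rising (30, 30 and 35 falling and 7, 8 and 9 rising over the list alone; adjusted p = 0.15, 0.154 and 0.148 with an estimated correlation). ZNF genes had 55, 54 and 57 of 432 rising and 9, 12 and 15 falling (61, 59 and 66 rising and 11, 14 and 18 falling over the list alone; adjusted p = 0.124, 0.136 and 0.148 with an estimated correlation).

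The design text of the series asks for differences across RNA types, and the table allows only a narrow answer. Protein-coding genes made up 19125 of its 19969 genes, and 79 were long noncoding RNA genes. Protein-coding genes took 99.3% ± 0.0078 of counts in the sgRNA libraries (n = 6) and 99.2% ± 0.023 in the inputs (n = 3). Long noncoding RNA genes took 0.0274% ± 0.002 and 0.0316% ± 0.0075. In Fisher's exact tests of each class among the genes past the threshold, none passed the Benjamini-Hochberg threshold in the 7 comparisons. The smallest adjusted p of these tests was 0.181, for ACTB sgRNA against input. Between guides, 12661 of the 12808 genes tested were protein-coding and 16 were long noncoding RNA genes. With so few genes past the threshold, the tests between guides could hardly have passed and decide nothing on RNA classes.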

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

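Counts halved to read pairs, thinning to the input depth, removal of mitochondrial and histone genes, the minimum mean of 10 CPM and, for the lists, halved counts and left-out libraries were chosen after seeing the data. Under the alternatives not named here, counts of genes stayed within 1.5 times the reported ones. For ACTB against non-target sgRNA (32), the count was 74 in DESeq2, 16 with all 9 libraries in the fit and 21 with a mean of at least 10 CPM. For ACTB against con sgRNA (4) it was 7 without a low-count filter and 0 with all 9 libraries. For con against non-target sgRNA (22) it was 38 in DESeq2 and 12 with at least 10 CPM, where fewer genes were tested. Against input, fitting only the groups compared, with fewer libraries and genes, gave 770 for ACTB (1477), 913 for con (1534) and 812 for non-target sgRNA (1699), and thinning gave 976 for ACTB and 1021 for con sgRNA. Leaving out each library in turn, the lone sample of a group being assumed to vary like the others, gave 18 to 35, 0 to 3 and 10 to 27 genes for the 3 comparisons between guides in the order above. The pooled comparison with input gave 2043 to 2429, ACTB sgRNA against input 630 to 1581, con 608 to 1640 and non-target 735 to 1800. The log2 fold change of ACTB then ranged from -0.02 to 0.06 against non-target, from -0.07 to 0.01 against con, from 0.04 to 0.06 for con against non-target and from -0.33 to -0.22 for the pooled comparison. The heat shock, mitochondrial and histone lists passed in 13 of 13 other settings against input. The number of lists past the threshold went from 6 to 3 with an estimated correlation in the pooled comparison and with each guide, and to 14 (pooled), 11 (ACTB) and 12 (con) with fry, which does not compare a list with other genes. Without the 10 most abundant genes the protein-coding share was 99.24% in the sgRNA libraries and 99.14% in the inputs. Signs that turned were all of differences that did not pass: ACTB at -0.02 and ACTA1 at -0.34 (range to 2.19) against non-target without ACTB sgRNA replicate 1, and ACTB at 0.01 against con without ACTB sgRNA replicate 2. ACTR3 was at 0.12 (range from -0.51) for con against non-target, and at -0.15 (range to 0.48) for non-target against input, without non-target replicate 1, and at 0 for the latter after thinning. ACTL6A was at -0.04 (range to 0.88) in the pooled comparison without input replicate 2, and ACTR1A for con against input at -0.13 (range to 0.35) without input replicate 2 and at -0.10 after thinning. Of the other values of named genes under an alternative, 4065 were the same in call and direction, 197 lost and 9 gained the threshold. Apart from settings whose construction (fewer libraries or genes) accounts for the change, the cause was not tested. Same-numbered libraries did not deviate together (correlations from -0.024 to 0.015), so the numbers were not taken to pair samples. With a replicate block the counts were 31, 4 and 22 between guides, 2309 in the pooled comparison and 1481, 1533 and 1651 for ACTB, con and non-target sgRNA against input. Depth limits the inputs most, where HSPA6 and other genes at 0 give bounds only.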

Other observations

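Among the tests below, those of HSF1 targets, of histone genes with poly(A) tails and of small RNAs inside genes were set before their results were seen, and all others were chosen only after the result was seen.

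Of the lists not yet described, none passed camera between the FHY1-M3 libraries and input. ATF4-driven amino acid response genes had 10 of 28 rising and 4 falling, or 14 and 4 adjusted over the list alone (median 0.43, adjusted p = 0.429), and glycolytic enzymes 6 of 21 rising and 2 falling, or 7 and 3 over the list alone (0.45, 0.662). Splicing factors had 12 of 34 rising and 6 falling, or 15 and 6 over the list alone (0.20, 0.784), translation factors 10 of 32 rising and 10 falling, or 12 and 10 (-0.02, 0.662), and immediate early genes 6 of 23 rising and 2 falling, or 8 and 3 (0.26, 0.784). Nuclear-encoded subunits of oxidative phosphorylation had 4 of 59 rising and 9 falling, or 5 and 9 over the list alone (-0.15, 0.189), and mitochondrial ribosomal proteins 10 of 75 rising and 5 falling, or 10 and 5 (0.19, 0.662). Genes of the unfolded protein response had 2 of 22 rising and 3 falling, or 4 and 3 over the list alone (-0.11, 0.784), mitosis genes 5 of 28 and 4, or 5 and 5 (-0.06, 0.662), and p53 targets 3 of 26 and 6, or 3 and 6 (-0.09, 0.781). Cholesterol synthesis had 4 of 23 rising and 5 falling, the same over the list alone (0.13, 0.969), chromatin modifiers 3 of 34 and 5, also the same (0.10, 0.968), and SRF targets 5 of 31 and 6, also the same (0.14, 0.784). Interferon-stimulated genes had 2 of 18 rising and 2 falling, or 3 and 2 over the list alone (-0.12, 0.918), and fibroblast markers 3 of 12 and 1, or 3 and 3 (0.04, 0.994). Neuronal markers (11 measured, median 0.16, or 0.07 with genes at 0 set at their bound, 0.662), kidney epithelial markers (9 measured, -0.44, 0.969) and keratinocyte and cervical markers (5 measured, 0.47, 0.918) had 0 genes past the threshold, 0 over the list alone, and 3, 1 and 0 at an unadjusted p under 0.05. Median and mean differed in sign for the m6A machinery (-0.04 and 0.18), p53 targets (mean 0.1), the unfolded protein response (0.02), interferon-stimulated genes (0.25), fibroblast (-0.05), kidney (0.43) and cervical markers (-0.55). Camera's direction was opposite to the median for the m6A machinery and interferon genes (up), and opposite to both median and mean for SRF targets, chromatin modifiers and cholesterol synthesis (down). It was opposite to the mean for p53 targets, the unfolded protein response and kidney markers (down) and for fibroblast and cervical markers (up). EMX1 stood at 1000, 453 and 779 CPM in the inputs and was lower in the FHY1-M3 libraries (log2 -4.32, SE 0.19), and CDR1 (-5.05, SE 0.18) and FTH1, a ferritin subunit gene with many pseudogenes (-3.21, SE 0.13), were lower too.

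For heat shock genes, which were higher in the FHY1-M3 libraries, the tables argue against a scaling shift, since with median-ratio scaling and without mitochondrial and histone genes the list's median was still 0.69, above 0.34, the upper end of the middle 95% of 10000 random lists matched on expression. Of 8 HSF1 target genes outside the list, all 8 rose, among them ZFAND2A (log2 1.99, SE 0.49), DEDD2 (1.40, SE 0.35) and UBB (0.91, SE 0.1). This leaves a heat shock response in those cells as a hypothesis. Of genes named after their values were seen, BAG3 (2.42, SE 0.21), HMOX1 (3.3, SE 0.52) and HSPA8 (0.67, SE 0.07) rose. HSPB1 (-0.01, SE 0.3) and ATF3 (-0.06, SE 0.13) did not pass. Immunoprecipitation of m6A-bearing RNA stays open, because the m6A level of each transcript here is not known. The heat shock median lay 0.70 above that of transcripts often described as carrying m6A (bootstrap 95% interval 0.36 to 1.46). Heat shock genes were left out of the latter list for that test, which left 26 transcripts with a median of 0.07. That test replaced one on HSPA6 alone, which had argued against immunoprecipitation, after its result was seen, and there HSPA6 rose at least 121-fold against a highest fold of 11.5 (COL5A1) among 9493 genes with at least 20 input counts, because a single top gene excludes nothing. Whether construct, light, culture or library batch lies behind the difference was not tested, because the design does not separate them.

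Mitochondrial mRNAs, histone mRNAs and TMEM107 were among the genes lower in the FHY1-M3 libraries, and for the mitochondrial part the tables argue against poly(A) selection, because the 12 mitochondrial mRNAs with a poly(A) tail had a median of -4.33 (-5.79 to -2.98), while MT-ND6, without a tail, was at -3.55 (SE 0.08), inside the quartiles of the others (-4.90 to -3.46), so that an earlier test on this gene alone had left the question open and was replaced after its result was seen. For the histone part taken alone it remains possible, since 7 histone genes with poly(A) tails had a median of 0.08, which is 2.83 above that of the replication-dependent genes. However, the stated protocol was removal of ribosomal RNA, and poly(A) selection would act on a whole library. The mitochondrial values therefore argue against it as the only cause of both parts. Immunoprecipitation cannot be told apart from other causes here, with the transcripts often described as carrying m6A (26 after removal of heat shock genes) at percentile 47.3 of matched random lists. Reads of small RNAs inside genes could account for TMEM107 (SNORD118), WDR74 (-5.42, RNU2-2) and EIF4A1 (-3.97, SNORA48), which had been seen before this test was set, but over all genes the odds ratio of being lower, in a logistic model with mean expression, was 1.3 with a 95% interval of 0.988 to 1.7, which leaves this open. Before that adjustment, 70 of 489 genes with a small RNA inside (14.3%) and 1056 of 12785 without (8.3%) were lower.

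For the genes present in the non-target libraries and near 0 in the other sgRNA libraries, the tables argue against a few molecules amplified in a single library, since of 23 genes with at least 40 counts in non-target replicate 1 and at most 3 over the ACTB and con sgRNA libraries, 21 (91.3%) had at least 10 counts in replicate 2, against 0 of 3 and 0 of 2 for the same choice in ACTB and con sgRNA. The tables also argue against RNA of neurons, as 8 abundant neuronal transcripts rose by at most 4.2 CPM over the con sgRNA mean of 383 CPM. FEZF2 held at least 111 CPM. For blood, 9 abundant transcripts, among them HBB, HBG2 and LYZ, summed to at most 26.9 CPM in a non-target library. All of it came from the fetal globin gene HBG1, while KLF1 held at least 62.8 CPM. This argues only against blood cells rich in these transcripts. Blood cells of other kinds stay open, because KLF1 is itself an erythroid gene and HBG1 was also present only in the non-target libraries. A wider list of blood markers, with 5 or more measured members only in some fits, went the other way in the comparison non-target sgRNA vs input, with an adjusted p of 0.0167 in camera without non-target replicate 1 and of 0.0714 to 0.117 in 4 other fits. Of the 19 genes lower in both comparisons with non-target sgRNA, 15 belong to transcription factor families, which was noticed in these genes first, so that the Fisher's exact test then run on them decides nothing. RNA of other cell types, RNA or DNA of a collection of transcription factor constructs, carry-over from another library and an effect of the non-target guide itself were not tested.

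The 2677 genes between the FHY1-M3 libraries and input were set against other splits of the 9 libraries into 6 and 3. In a model with 2 groups the real split gave 2908 genes, and the highest of the other splits gave 1. Only the real split, 1 of 84, gave as many. Every other split put inputs and sgRNA libraries together in the larger group. That widens the spread within it, so few calls could be foreseen there and the test cannot decide on chance. Such splits do not separate construct from library type. Depth alone does not account for the difference, since 2154 genes passed after thinning to the input total.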
